A study of Mus with 6 samples.

How the data were processed

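The samples were 6 RNA-seq libraries of basolateral amygdala, the part of the amygdala that receives sensory and cortical input, from mice labelled female. The labels put 3 libraries in a wild-type group (WT) and 3 in a Cntnap4 knockout group (KO), and number them 1 to 3 in each. The labels do not describe the knockout allele, the strain or the age, and do not state that each library came from a separate animal. The p-values therefore set the difference between groups against the spread between these libraries, which may not be the spread between animals. Per the labels' protocols, RNA was extracted with a Qiagen column kit and libraries were made with a SMARTER mRNA kit.

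The deposited table gave FPKM (fragments per kilobase of gene, scaled by library size) for 54532 Ensembl genes in the 6 libraries, with each gene's name, position, length and biotype per the file headers. The genome builds named in the submitters' processing notes are GRCm38 and mm10, and positions are printed as the table gives them. The aligner, the counter, the annotation version and the use of strand are not given in the sources used here. Multiplying each FPKM by the gene's length gave whole multiples of 1 step per library for 100% of values, within a tolerance of 0.01 reads, so the number of reads behind each value was recovered. The recovered reads summed to between 15933029 and 17789798 per library. The library sizes that the steps imply were 0.964 to 1.05 times those sums, so the authors' values carry a scaling factor between libraries. The data were not treated as counts in the main test.

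Genes with a mean FPKM of at least 1 over the 6 libraries were tested, which left 13087 genes, 11815 of them protein coding. Values were taken as log2(FPKM + 1), so a fold change is on that scale and understates the change of genes with low values. KO was compared with WT with limma 3.58.1 in R 4.3.3 (linear model, empirical Bayes with a variance trend, two-sided), adjusted by the Benjamini-Hochberg method over all genes tested, with a threshold of 0.05. Every adjusted p given for a gene comes from this fit unless stated. Values are given as mean ± SD over the 3 libraries of a group, and SE is the moderated standard error of the log2 fold change. For a single gene, 3 libraries against 3 cannot give an exact permutation p below 0.1.

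Before the data were examined, 48 gene lists were fixed for cell types of the amygdala, neighbouring tissues a dissected piece can hold, synapse and channel families, signalling and metabolic pathways, high-confidence autism genes and sex-linked transcripts. The table held 1141 of their 1144 symbols. The 44 lists with at least 5 tested members were tested against the other genes with limma's camera (preset correlation of 0.01 between genes), adjusted over the 44 lists. The test was repeated with a correlation estimated for each list and with fry, which asks whether a list's genes move one way on balance. Genes whose midpoint lies within 10 Mb of Cntnap4 were tested as 1 more list, since a targeted allele can carry flanking sequence of another strain. In the text a list is said to be lower or higher when camera with the preset correlation called it. A gene's p adjusted over the list alone covers the tested members of that list and is not corrected across the 48 lists.

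Genes were named by a rule set before the data were examined. It took the Cntnap family; the 12 lower and 12 higher genes whose 3 KO values all lay on one side of the 3 WT values, those past the threshold first by size of change and then those of smallest p, leaving out pseudogenes and genes with only a model or clone name; up to 4 members of smallest p from each called list and each marker list; 3 members from 6 lists of neuronal signalling; and Xist with the Y-linked genes. Some genes that the rule takes are not reported here. Genes named outside the rule are said to have been chosen after their values were seen. Means, positions and values per library come from the same table.

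The tests were tried on simulated data with this design before use. Of 65 genes changed 1.5-fold, 24.6% were recovered among 12923 genes, against 79.0% of 62 genes changed 2-fold and 95.2% of 63 genes changed 4-fold; 13 of 12693 unchanged genes were called. A planted list was called and 0 of 44 others were. Simulated genes were drawn independently, each with the median spread of genes at its level. Shared shifts between libraries and genes of larger spread were left out, so the shares recovered may overstate recovery in these data. The many planted changes also made the Benjamini-Hochberg threshold easier to pass than in the real fit, where 1 gene passed. The shares are therefore not the power of that fit. Nor can the simulation show how the list test behaves with correlated members, such as the 0.675 estimated for the microglial list.

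Whether the replicate numbers pair the libraries was checked by correlating deviations from the group means across genes. Libraries with the same number gave r of 0.175, 0.145 and 0.330, all above 0.1, so a fit with the number as a block is given where it changes a call. The labels do not say what a number shares, deviations within a group of 3 are not independent of each other, and WT2 correlated better with KO1 (0.283) than with KO2. No 2 libraries agreed within sampling noise, with a chi-square per gene of at least 13.7 for every pair.

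The analysis was repeated with other pseudocounts, filters, scalings and variance models, sample weights, the replicate block, other windows, and leaving out each library. Voom on the recovered reads, removal of the trend with gene length from each library, and leaving out WT3 with KO3 were chosen after seeing the data. GC content was not tested, since no genome sequence was used here. Figures were drawn with matplotlib 3.10.9.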

Results

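Gene expression was measured in the basolateral amygdala of wild-type (WT, 3 libraries) and Cntnap4 knockout (KO, 3 libraries) mice labelled female. Cntnap4 encodes a contactin-associated transmembrane protein of the neurexin superfamily found in interneurons. The series title concerns fear memory and a Lactobacillus species, but no sample labelled with a bacterial treatment was analysed here, so the data address 1 comparison, KO against WT. The libraries held 15933029 to 17789798 recovered reads, and 22166 to 23375 genes had a value above 0. Xist, the transcript of the inactive X chromosome, was present in all 6 libraries at 23.3 to 50.1 FPKM, and the 7 Y-linked genes listed had 0 reads.

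Cntnap4 itself was lower in every KO library than in every WT library. Its level was 3.20 ± 0.92 FPKM in WT (3.53, 3.90 and 2.15) and 1.18 ± 0.10 in KO (1.08, 1.19 and 1.28), a ratio of 0.370. The gene (ENSMUSG00000031772) lies on chromosome 8 from 112570043 to 112882717. The log2 fold change was -0.92 (SE 0.18), and with an adjusted p of 0.302 over 13087 genes it did not pass the threshold. Adjusted over the list alone, among the 34 tested genes of a list of contactins, Cntnap genes, neurexins, neuroligins and other synaptic adhesion genes, the adjusted p was 0.0307. The remaining KO signal cannot be assigned to exons, since the values are per gene and the deleted part is not described in the labels. Over all genes 0 members of this list passed, and 4 passed adjusted over the list alone, Cntnap4 (lower) and 3 others (higher), none of them another Cntnap gene. Cntnap2, a cell adhesion gene linked to autism, was at 11.5 ± 1.44 FPKM in WT and 13.02 ± 0.98 in KO. Cntnap1, a protein of the paranodal junction of myelinated axons, was at 40.4 ± 10.6 and 45.8 ± 3.86, and without WT1 its log2 fold change went from 0.21 to -0.02. Cntnap3 was at 2.41 ± 0.31 and 1.80 ± 0.58, Cntnap5a at 5.53 ± 1.60 and 4.74 ± 0.84, and Cntnap5b at 1.51 ± 0.09 and 1.42 ± 0.35, where the log2 fold change of -0.06 went to 0.02 without KO2. Cntnap5c, at 0.91 ± 0.37 and 0.60 ± 0.23, was below the filter.

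**Figure D1:**
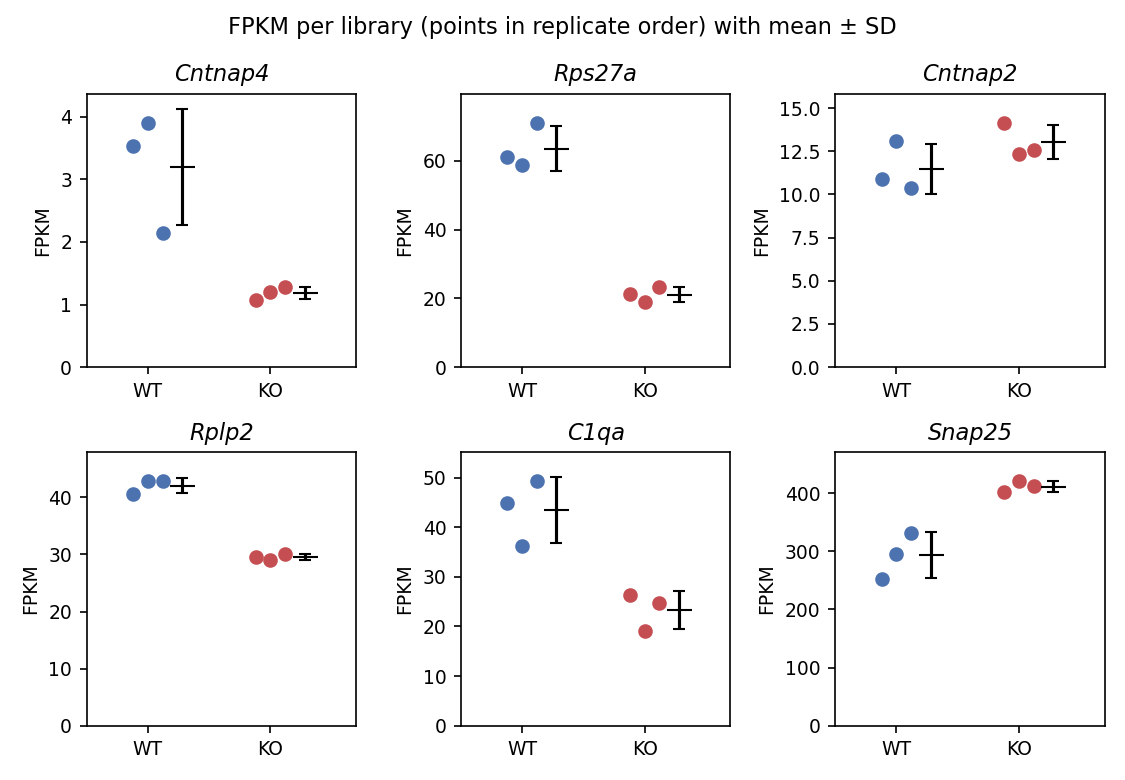
FPKM of 6 genes in each library (points) with the group mean ± SD (black); the vertical axes start at 0. Cntnap4 sits at 2.15 to 3.90 in WT and 1.08 to 1.28 in KO, and Rps27a at 58.7 to 71.1 in WT and 18.9 to 23.3 in KO.

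Rps27a was the gene that fell in KO past the threshold. It encodes a fusion of ubiquitin with a protein of the small ribosomal subunit. Its level was 63.6 ± 6.58 FPKM in WT and 21.1 ± 2.22 in KO, a ratio of 0.332, with no overlap between the groups. The gene (ENSMUSG00000020460) lies on chromosome 11 from 29545846 to 29548109. The log2 fold change was -1.55 (SE 0.12, limma adjusted p = 0.0461), and about 2158 recovered reads per WT library and 696.3 per KO library stood behind it. The adjusted p was 0.0702 with the replicate block, 0.156 to 0.499 without any one of the libraries other than WT3, and 0.0392 without WT3. It was 0.134 with no filter, 0.0864 with quantile normalization and 0.0675 with no variance trend. With the length trend removed it was 0.0786, and 0.132 with both libraries numbered 3 left out. In all, Rps27a passed in 8 of 19 alternatives.

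Across the genome, 1 of 13087 genes passed the threshold in limma, and the next smallest adjusted p was 0.302. With voom on the recovered reads 1 gene passed. At an unadjusted p under 0.05 there were 1872 genes, 923 higher and 949 lower in KO, where 654.4 would be reached by chance. With values rescaled to 1 common sum per library the split was 1217 higher and 579 lower. The 3 KO values lay outside the range of the 3 WT values for 22.0% of genes (1556 higher, 1324 lower), against 10% by chance. Both chance figures are averages, and genes that shift together can move a single grouping far from them. Other splits of the 6 libraries into 3 and 3 gave 169 to 1554 genes at an unadjusted p under 0.05. The nominal count was 1245 without WT1 and 879 without KO2. Without WT3, 9 genes passed, 4 higher and 5 lower, among them Trh.

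None of the following genes passed the threshold; they had the smallest p among those with no overlap between groups. Doc2b, a calcium sensor of vesicle release, was at 14.2 ± 4.34 FPKM in WT and 4.16 ± 1.58 in KO, with a log2 fold change of -1.56 (SE 0.26). Sncg, a synuclein, was at 2.43 ± 0.14 and 0.72 ± 0.29. Naa38, a subunit of an N-terminal acetyltransferase, was at 15.3 ± 1.76 and 8.46 ± 0.98, and Tomm7, part of the import pore of the outer mitochondrial membrane, at 11.4 ± 0.86 and 7.26 ± 0.47. The histone H4 gene Hist1h4i was at 1.86 ± 0.14 and 0.50 ± 0.23, the mitochondrial carrier Slc25a34 at 3.66 ± 0.32 and 1.71 ± 0.16, and the peroxisome assembly gene Pex16 at 10.8 ± 0.24 and 7.40 ± 0.22. Few reads stood behind Hist1h4i and Sncg, with means of 14.7 and 23 recovered reads per library. Sowaha (51.0 ± 5.16 and 29.7 ± 3.93), Tspan4, Npm3 and Gstm6 completed the 12 with Rps27a, at ratios of 0.583, 0.661, 0.489 and 0.468.

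Higher in KO without passing the threshold were Vxn, at 84.1 ± 17.8 FPKM in WT and 146 ± 9.61 in KO, and Slc38a2, a neutral amino acid transporter, at 16.4 ± 1.83 and 24.1 ± 1.72. Cdh18, a cadherin, was at 3.15 ± 0.11 and 5.03 ± 0.37, and Nyap2, a phosphoinositide 3-kinase adaptor of neurons, at 3.35 ± 0.08 and 5.24 ± 0.36. Wee1, a kinase that holds the cell cycle before mitosis, was at 7.14 ± 0.51 and 10.5 ± 0.38. Sacm1l, a phosphoinositide phosphatase, was at 7.61 ± 1.05 and 11.8 ± 0.40. Krtcap3, Fv1, Tmem196, Ppip5k1, Adam9 and Zfp260 completed the 12, at ratios between 1.36 (Adam9) and 2.45 (Krtcap3). Krtcap3 rested on a mean of 31.7 recovered reads per library.

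Of the 44 gene lists tested, camera with the preset correlation called 16, 12 lower and 4 higher in KO. With a correlation estimated for each list 0 were called (smallest adjusted p = 0.0808), and fry called 1, the nuclear genes of oxidative phosphorylation (adjusted p = 0.0126). With the replicate block fry called 0 (0.124 for that list) and camera with the preset correlation called 20, adding the striatal (adjusted p = 1.22e-06), dopamine (0.000517), myelin (0.0109) and border macrophage lists (0.0217). Of these added lists, myelin was higher in KO and the rest lower. Members of the striatal and dopamine lists were on average highest in WT3 and KO3. With the block and an estimated correlation 0 lists were called, and the adjusted p of the added lists, in the order given, was 0.816, 0.745, 0.852 and 0.816.

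Genes of the cytosolic ribosome were lower in KO as a group. Of 76 tested ribosomal protein genes, 74 had a negative log2 fold change, with a median of -0.30, and 49 had all KO values below all WT values. Rplp2, of the ribosomal stalk, was at 42.1 ± 1.28 FPKM in WT and 29.5 ± 0.53 in KO, Rpl36 at 150 ± 6.55 and 97.3 ± 9.71, and Rps2 at 141 ± 13.01 and 95.3 ± 3.31. The list had an adjusted p of 4.89e-21, and an adjusted p of 0.688 with an estimated correlation. Over all genes 1 member (Rps27a) passed, and 34 passed adjusted over the list alone, all lower. The authors' handling of reads shared with the many pseudogenes of this family is not given in the sources used here.

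Nuclear genes of oxidative phosphorylation were also lower, by less, and by about as much as protein-coding genes of like length. Of 72 tested, 62 had a negative log2 fold change, with a median of -0.17 (adjusted p = 1.97e-07; adjusted p = 0.0808 with an estimated correlation). Their median length was 1709.5 bases, and protein-coding genes of 1000 to 2000 bases also had a median of -0.17. With the trend with gene length removed the list's median was -0.07 and its adjusted p 0.0434. Ndufa13, of complex I, was at 54.2 ± 2.21 FPKM in WT and 37.3 ± 4.49 in KO, Uqcr11, of complex III, at 48.2 ± 3.64 and 33.3 ± 4.22, Cox5b, of complex IV, at 48.3 ± 1.33 and 35.7 ± 3.63, and Ndufa2 at 74.1 ± 5.64 and 56.2 ± 3.28. No member passed over all genes or adjusted over the list alone (0 in each), with 18 nominally lower. The 15 listed genes encoded in mitochondrial DNA were all lower on average, with a median of -0.30, but their levels followed WT3. There all genes placed on mitochondrial DNA, listed or not, took 8.34% of reads against 4.10% to 6.31% in the other libraries. The adjusted p of the 15 listed genes was 0.0346 (adjusted p = 0.797 with an estimated correlation; 0 members passed adjusted over the list alone). It was 0.240 without KO1, 0.165 without KO2, 0.185 with the length trend removed, 0.178 with no filter and 0.0875 with sample weights. Without WT3 the direction of the test turned (0.944) while the median was -0.03, and the median was -0.45 without WT2 and without KO3. mt-Atp6 was at 350 ± 239 and 149 ± 19.0, mt-Nd6 at 3359.5 ± 970.1 and 2482 ± 572, mt-Co2 at 247 ± 120 and 170 ± 46.7 and mt-Cytb at 7777 ± 2824 and 5930 ± 1323.

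Microglial and immune genes were lower in KO. All 22 tested microglial markers had a negative log2 fold change (median -0.34, adjusted p = 1.97e-07; adjusted p = 0.707 with an estimated correlation), and 0 passed over all genes and 7 adjusted over the list alone. Without WT3 the median was -0.22 (adjusted p = 0.00203). C1qa and C1qb, chains of the first complement component, were at 43.4 ± 6.65 and 41.6 ± 6.68 FPKM in WT and 23.4 ± 3.85 and 25.9 ± 2.17 in KO. Fcrls, a microglial receptor, was at 11.5 ± 3.12 and 6.09 ± 0.63, and Tyrobp, a signalling adaptor, at 10.8 ± 1.86 and 6.71 ± 0.49. All 12 complement and class I histocompatibility genes were lower on average (median -0.37, adjusted p = 5.79e-07; adjusted p = 0.688 with an estimated correlation; 5 passed adjusted over the list alone). Among them H2-K1 was at 17.5 ± 1.62 and 11.5 ± 0.69, and the complement inhibitor Serping1 at 4.24 ± 1.19 and 2.09 ± 0.53. C1qa and C1qb are members of both lists.

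Interferon-response genes were lower for 13 of 15 (median -0.43, adjusted p = 0.00216; adjusted p = 0.765 with an estimated correlation; 2 passed adjusted over the list alone), but without WT3 the median was -0.07 and the adjusted p 0.207, and without WT2 the median was -0.78. The adjusted p was 0.107 with both libraries numbered 3 left out and 0.151 with sample weights. Isg15 was at 3.82 ± 1.32 FPKM in WT and 1.30 ± 0.51 in KO, Ifitm3 at 18.8 ± 7.81 and 8.31 ± 1.20, Lgals3bp at 5.83 ± 1.89 and 3.49 ± 0.36 and Gbp3 at 2.14 ± 0.91 and 0.96 ± 0.14. All 9 genes of reactive glia and cytokines were lower on average (median -0.41, adjusted p = 0.00216; adjusted p = 0.524 with an estimated correlation; 1 passed adjusted over the list alone). Apoe, the lipid carrier of glia, was at 648 ± 52.9 and 395 ± 30.3 with no overlap. Cd68, Spp1 and Gfap overlapped between the groups, and Gfap was at 54.2 ± 33.5 and 28.8 ± 13.9 with 92.8 in WT1. The mean deviation of the microglial list was 0.49 in WT3 and that of the interferon list 0.62, both the highest of the 6 libraries.

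Markers of oligodendrocyte precursors, astrocytes, pericytes and meninges were lower in KO as well. Of 14 precursor markers 13 were lower on average (median -0.37, adjusted p = 2.02e-05; adjusted p = 0.524 with an estimated correlation; 1 passed adjusted over the list alone). C1ql1 was at 8.11 ± 2.11 FPKM in WT and 3.57 ± 0.29 in KO, Pdgfra, the growth factor receptor that marks these cells, at 8.21 ± 1.33 and 5.61 ± 0.95, Lhfpl3 at 9.45 ± 2.17 and 6.30 ± 0.61 and Cacng4 at 15.2 ± 4.36 and 8.15 ± 2.80. Of 20 astrocyte markers 18 were lower on average (median -0.22, adjusted p = 0.00471; adjusted p = 0.765 with an estimated correlation; 0 passed adjusted over the list alone), with Mlc1 at 62.2 ± 8.08 and 48.4 ± 4.28, Slc6a11 at 35.5 ± 0.75 and 29.3 ± 3.37 and the water channel Aqp4 at 22.3 ± 5.31 and 15.2 ± 3.88. The astrocyte call was lost without WT3 (0.290) and without KO1 (0.0878).

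Pericyte and smooth muscle markers were lower on average for 13 of 14 (median -0.37, adjusted p = 0.000769; adjusted p = 0.707 with an estimated correlation; 1 passed adjusted over the list alone), and the adjusted p was 0.152 without WT3. Ndufa4l2 was at 4.05 ± 0.45 FPKM in WT and 1.97 ± 0.46 in KO, Myh11, the smooth muscle myosin, at 3.07 ± 1.30 and 1.42 ± 0.06, Cspg4 at 2.43 ± 0.24 and 1.64 ± 0.37 and Vtn at 44.0 ± 12.5 and 28.7 ± 3.33. Meningeal fibroblast markers were lower for 16 of 18 (median -0.60, adjusted p = 3.91e-05; adjusted p = 0.765 with an estimated correlation; 0 passed adjusted over the list alone). The mean deviation of that list was 0.84 in WT1, the highest of the 6 libraries, and 0.06 in KO1, and without WT1 the median was -0.29 (adjusted p = 0.0150). Slc6a13 was at 4.06 ± 1.039 and 2.10 ± 0.24, Slc13a3 at 4.36 ± 1.55 and 1.97 ± 0.73, Dcn at 5.93 ± 3.67 and 1.74 ± 0.55 and Igfbp2 at 23.6 ± 9.92 and 11.3 ± 5.98. Dcn is also a member of the basolateral amygdala projection neuron list, and was at 9.17 in WT1, 6.68 in WT2 and 1.95 in WT3. Myelin genes were not called (median 0.30, adjusted p = 0.104), nor were endothelial genes (median -0.12, adjusted p = 0.132), border macrophages (median -0.90, adjusted p = 0.0750) or haemoglobin genes (median -0.37, adjusted p = 0.414), and 0 members of these lists passed adjusted over the list alone. With 1 library left out the preset correlation called some of them: myelin genes without WT3 (2.18e-05) and without KO1 (0.00977), endothelial genes without WT1 (0.000857), WT2 (0.0155) and KO3 (0.0126), border macrophages without WT1 (0.0251) and KO3 (0.0189), and haemoglobin genes without WT1 (0.0271). Of the 26 tested members of the myelin list, 18 had a positive log2 fold change and 8 a negative one. Among the 8 were the lineage factors Olig1 and Olig2, at 68.9 ± 7.63 and 12.7 ± 2.08 in WT and 54.8 ± 2.77 and 8.85 ± 1.71 in KO. Of the endothelial list, Cdh5 was at 4.49 ± 0.61 and 3.74 ± 0.17 and the glucose transporter Slc2a1 at 50.5 ± 3.56 and 42.6 ± 8.74. The class II histocompatibility genes H2-Aa and H2-Ab1 of the macrophage list were at 2.28 ± 1.53 and 1.92 ± 1.39 in WT and 0.50 ± 0.19 and 0.45 ± 0.19 in KO.

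**Figure D2:**
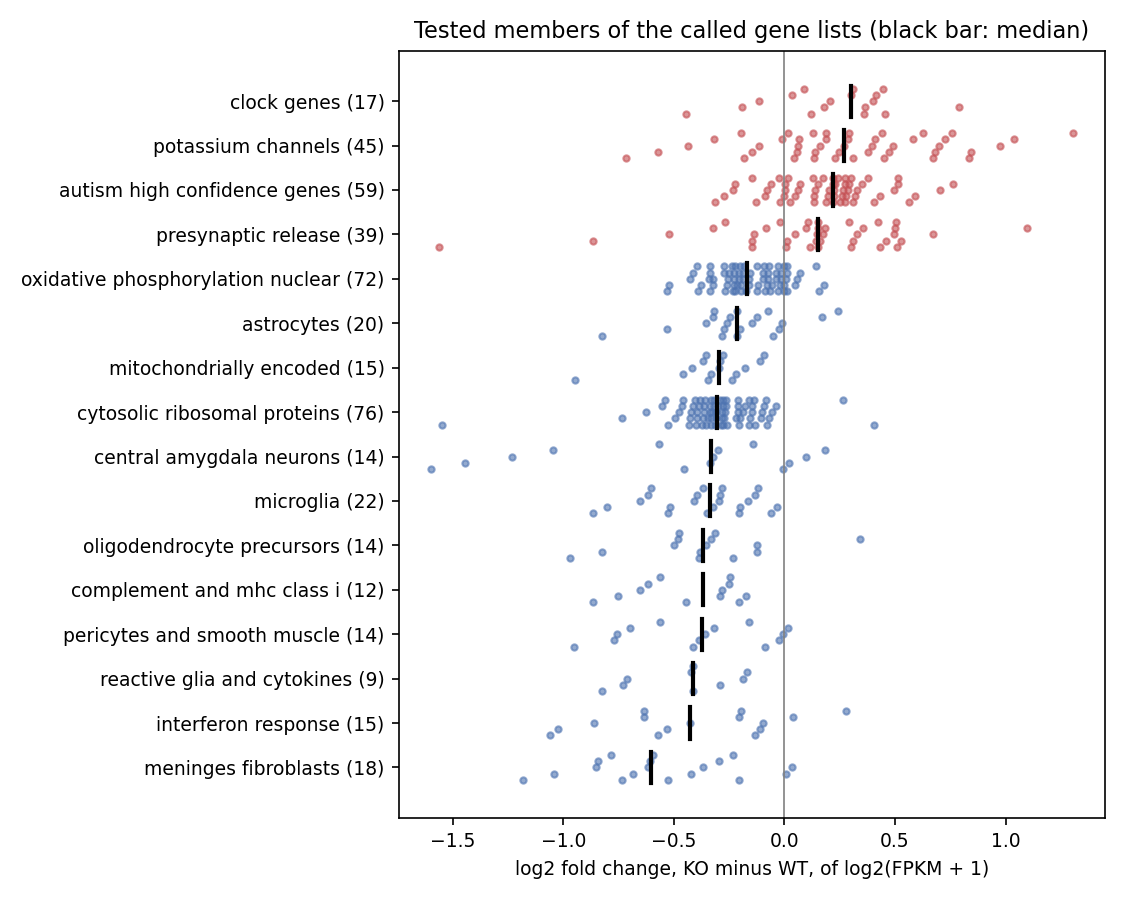
Log2 fold change (KO minus WT, on the log2(FPKM + 1) scale) of each tested member of the 16 called gene lists, with the number of members in brackets, the median as a black bar, and blue for lists lower and red for lists higher in KO. Medians run from -0.60 (meninges fibroblasts) to 0.30 (clock genes).

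Potassium channel and presynaptic release genes were higher in KO as groups. Of 45 potassium channel genes 36 had a positive log2 fold change (median 0.27, adjusted p = 6.40e-05; adjusted p = 0.707 with an estimated correlation; 0 passed adjusted over the list alone). Without WT1, where the mean deviation of this list was -0.44, the median was 0.17 (adjusted p = 8.20e-05). Kcnh1 was at 9.87 ± 2.11 FPKM in WT and 16.6 ± 2.89 in KO, Kcnt2 at 4.54 ± 1.42 and 8.18 ± 1.08 and Kcnj3 at 20.5 ± 1.71 and 27.3 ± 2.59, while Kcnn3, a calcium-activated channel, was at 3.01 ± 0.35 and 1.73 ± 0.53. Presynaptic release genes were higher on average for 29 of 39 (median 0.15, adjusted p = 0.0346; adjusted p = 0.765 with an estimated correlation), with Snap25, of the vesicle fusion complex, at 293 ± 39.5 and 411 ± 9.57 and Pclo, an active zone scaffold, at 10.6 ± 1.87 and 15.3 ± 1.14. The 1 member that passed adjusted over the list alone was Doc2b, which was lower, and Unc13c was at 7.20 ± 1.19 and 3.58 ± 1.17. The presynaptic call was lost without WT3 (0.129), without KO1 (0.274), with the length trend removed (0.150), with a mean FPKM of at least 5 (0.0955) and with sample weights (0.135), and its median was 0.09 without WT1 and 0.25 without KO3.

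High-confidence autism genes were higher on average for 47 of 59 (median 0.22, adjusted p = 7.05e-06; adjusted p = 0.765 with an estimated correlation; 0 passed adjusted over the list alone). Cul3 was at 29.8 ± 0.92 FPKM in WT and 36.5 ± 0.78 in KO, the chromatin gene Ash1l at 10.4 ± 2.17 and 14.9 ± 0.86, and Tbr1, a transcription factor of cortical projection neurons, at 28.5 ± 7.93 and 46.1 ± 6.43. With the trend with gene length removed the median of this list was 0.05 and the adjusted p 0.150. Clock genes were higher for 14 of 17 (median 0.30, adjusted p = 0.0346; adjusted p = 0.765 with an estimated correlation; 0 passed adjusted over the list alone). Clock was at 6.12 ± 0.81 and 8.45 ± 0.55, Per3 at 4.02 ± 0.37 and 5.86 ± 0.88, Nr1d2 at 24.9 ± 3.34 and 32.0 ± 2.44 and Hlf at 36.2 ± 14.8 and 59.3 ± 3.43. The clock call was lost without WT1 (0.113), without KO1 (0.274), with the length trend removed (0.0692), with a mean FPKM of at least 5 (0.145) and with sample weights (0.216), and the labels give no time of collection.

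Neurotransmitter receptor and interneuron lists did not pass. GABA receptor genes (21 tested, median 0.15) had an adjusted p of 0.196, with Gabrb2 at 15.6 ± 5.82 FPKM in WT and 25.4 ± 2.22 in KO. Interneuron markers (30 tested, median -0.04) had 0.762, with Nos1 at 9.28 ± 3.60 and 4.13 ± 0.73, Kcnc2 at 14.1 ± 4.07 and 21.8 ± 2.68, the vesicular GABA transporter Slc32a1 at 49.5 ± 5.46 and 38.2 ± 4.27 and Sst, the peptide somatostatin, at 316 ± 103 and 206 ± 15.4. Ionotropic glutamate receptor genes (26 tested, median 0.00) had 0.966, with the receptor auxiliary subunit Cnih2 at 212 ± 32.4 and 141 ± 5.89, Grin2a at 8.06 ± 1.74 and 12.1 ± 0.51 and Gria4 at 12.9 ± 1.33 and 16.3 ± 0.74. Glutamatergic neuron markers (15 tested, median 0.09) had 0.343, with Neurod6 at 14.1 ± 6.13 and 30.0 ± 3.67, Chrm3 at 7.27 ± 2.50 and 13.3 ± 2.05 and Lmo3 at 41.0 ± 18.1 and 20.8 ± 4.28. Over these lists 0 members passed adjusted over the list alone.

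Immediate early genes (31 tested, median 0.21) had an adjusted p of 0.348 and were highest in 1 library of each group, with a mean deviation of 0.62 in WT2 and 0.73 in KO1. Gadd45g was at 11.7 ± 2.05 FPKM in WT and 6.36 ± 1.34 in KO, Ier5 at 34.6 ± 13.1 and 53.1 ± 18.9 and Npas4 at 3.85 ± 2.62 and 5.80 ± 1.21. Neuropeptide genes (32 tested, median -0.08) had 0.450, with the oxytocin receptor Oxtr at 3.71 ± 1.69 and 1.34 ± 0.62 and Sstr4 at 7.69 ± 2.90 and 12.9 ± 3.76. Dopamine signalling genes (10 tested, median -0.31) had 0.176, with Maoa at 9.09 ± 1.41 and 7.42 ± 0.63, Adcy5 at 61.2 ± 41.8 and 33.8 ± 16.8 and Gnal at 40.8 ± 19.9 and 30.9 ± 13.7. The immediate early list was called without WT2 (5.00e-05) and the dopamine list without WT2 (0.0168) and without KO3 (0.0126). The dopamine list was high in WT3 and KO3, with mean deviations of 1.037 and 0.518 against -0.08 to -0.56 elsewhere. The striatal markers described below were high in the same libraries. Adcy5 and Gnal were also highest in WT3 and KO3, while Maoa was highest in WT1. In each of these 3 lists 0 members passed adjusted over the list alone.

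The other lists tested did not pass either. Adjusted p was 0.212 for postsynaptic scaffolds, 0.450 for metabotropic glutamate receptors, 0.251 for serotonin and acetylcholine signalling, 0.289 for sodium and calcium channels, 0.342 for glucocorticoid response, 0.508 for neurotrophin signalling, 0.838 for Wnt signalling, 0.731 for the cytoskeleton, 0.605 for chaperones, 0.731 for the unfolded protein response and 0.212 for cholesterol synthesis. With 1 library left out, postsynaptic scaffolds were called without KO3 (0.0298), glucocorticoid response without WT2 (0.00322) and cholesterol synthesis without WT3 (0.0399). In these 11 lists 0 members passed adjusted over the list alone. The median and the mean differed in sign for ionotropic glutamate receptors, the cytoskeleton and the unfolded protein response.

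Markers of neighbouring tissue differed between libraries of the same group. Striatal genes were high in WT3 and KO3, with mean deviations of 1.88 and 0.95 against -0.54 to -0.88 in the other libraries. Drd2, the dopamine receptor of striatal projection neurons, was at 56.5 FPKM in WT3 and 20.6 in KO3 and at most 2.06 elsewhere, and Adora2a was at 51.2 and 14.7 and at most 1.90 elsewhere; both were chosen after their values were seen. The striatal list was not called (22 tested, median -0.49, adjusted p = 0.122) but was without WT1 (0.00257), WT2 (0.00479) or KO3 (0.000140), with Penk at 144 ± 103 in WT and 39.7 ± 50.8 in KO, Bcl11b at 18.4 ± 4.68 and 12.7 ± 1.69, Six3 at 2.15 ± 1.94 and 0.63 ± 1.03 and Foxp1 at 6.11 ± 4.91 and 9.06 ± 0.99. The 4 tested genes of the hypothalamic list had their highest values in WT1 and WT2. Trh was at 18.7 and 21.6 in these and at most 2.02 elsewhere, Baiap3 at 20.6 and 10.98 and at most 2.52 elsewhere, and Avp, the vasopressin gene, at 11.3 and 2.16 and at most 0.62 elsewhere, while Peg10 was at 6.98 ± 4.27 in WT and 3.96 ± 1.20 in KO (11.6 in WT1 and 6.20 in WT2, and at most 5.34 elsewhere). Of 18 listed genes with a value above 0, WT1 and WT2 were the highest libraries in 9. Chosen after their values were seen, Otp was at 2.19 and 0.52 in these and at most 0.04 elsewhere and Gal at 1.95 and 0.53 and at most 0.51 elsewhere, whereas Nkx2-1 was at 1.08 in WT3 against 0.64 and 0.55 in WT1 and WT2, and Pomc at 1.03 against 0.77 and 0.95, while Agrp was at 0.50 ± 0.03 in WT and 0.49 ± 0.27 in KO. With no filter, the 18 genes were called lower in KO with the preset correlation (median -0.50, adjusted p = 0.000121).

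Central amygdala markers were lower in KO for 11 of 14 (median -0.33, adjusted p = 0.0182; adjusted p = 0.707 with an estimated correlation; 0 passed adjusted over the list alone), and the adjusted p was 0.0974 without KO2. With a mean FPKM of at least 5, which left 8 members, the median was -0.15 and the adjusted p 0.360. The mean deviation of that list was 0.57 in WT1 and 0.27 in WT2, but -0.07 in WT3. It was -0.26 in KO1, -0.51 in KO2 and -8.9e-05 in KO3, so WT3 lay below KO3. Calcrl was at 1.88 ± 0.12 FPKM in WT and 1.29 ± 0.20 in KO, Nts, the neurotensin gene, at 4.61 ± 4.64 and 0.63 ± 0.52 and Dlk1 at 5.22 ± 4.97 and 0.51 ± 0.34. Basolateral amygdala projection neuron markers were not called (14 tested, median -0.07, adjusted p = 0.414, and 0.0185 without WT3), with Cyp26b1 at 3.83 ± 3.21 and 0.75 ± 0.42, Cdh13 at 8.60 ± 0.88 and 6.43 ± 1.14 and Otof at 5.13 ± 2.60 and 1.97 ± 0.70. The mean deviation of the basolateral list was 0.26 in WT1, 0.39 in WT2 and -0.36 in WT3, against -0.02 to -0.17 in the KO libraries. Piriform and neocortical markers (15 tested, median 0.19) had 0.342, with Fezf2 at 9.25 ± 6.03 and 18.9 ± 6.79 and Calb1 at 43.4 ± 19.0 and 24.2 ± 6.42, and thalamic markers (7 tested, median -0.06) had 0.528, with Ntng1 at 3.14 ± 0.96 and 2.30 ± 0.17 and Ramp3 at 6.51 ± 2.61 and 10.8 ± 4.73. Of choroid plexus and ependymal markers 4 and 3 were tested, with Ttr at 25.5 ± 17.0 and 14.5 ± 10.3, Enpp2 at 26.0 ± 9.41 and 38.8 ± 2.44, Rsph1 at 2.38 ± 0.96 and 0.92 ± 0.33 and Foxj1 at 1.65 ± 0.36 and 1.65 ± 0.23. Adjusted over the list alone, Rsph1 was the 1 member that passed, and 0 passed in the striatal, hypothalamic, basolateral, cortical, thalamic and choroid plexus lists. Haemoglobin genes had a mean deviation of 1.07 in WT3; Hbb-bs was at 119 ± 74.4 and 94.98 ± 10.95, and its log2 fold change of -0.16 went to 0.31 without WT3, while Hba-a1 was at 106 ± 74.1 and 70.5 ± 5.65 and went from -0.37 to 0.16.

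**Figure D3:**
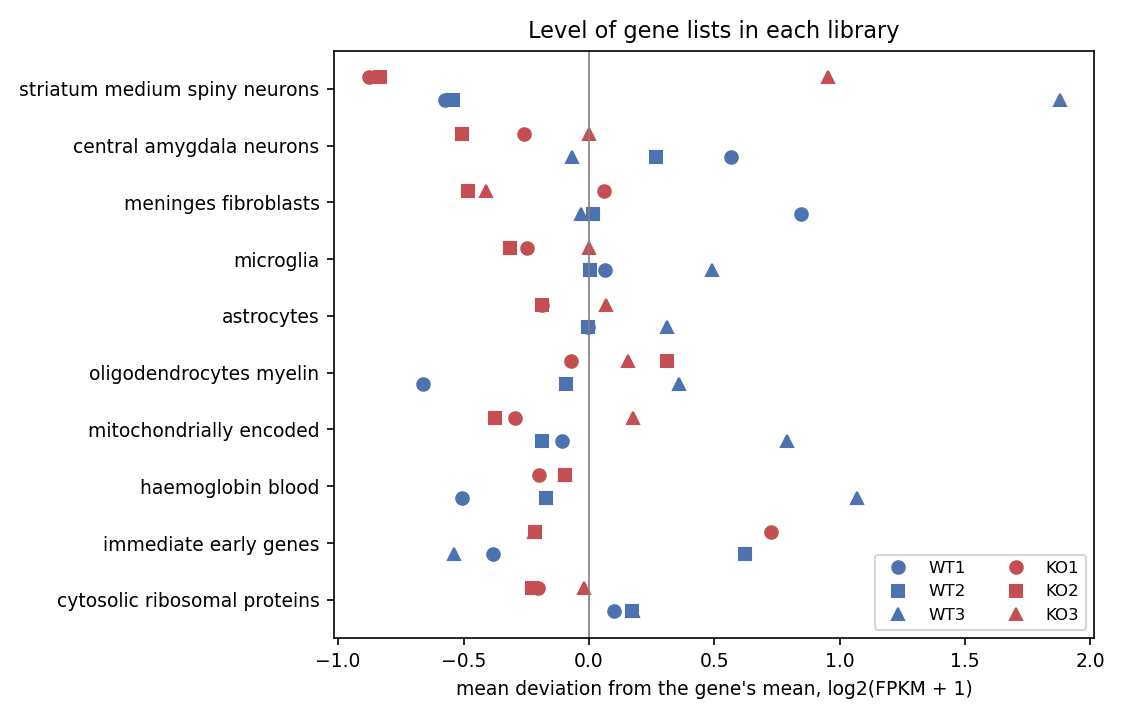
Mean over list members of the deviation of log2(FPKM + 1) from each gene's mean over the 6 libraries, for 10 gene lists (blue WT, red KO; marker shape gives the replicate number). The striatal list sits at 1.88 in WT3 and 0.95 in KO3, and in the ribosomal list every WT library lies at 0.10 or above and every KO library at -0.02 or below.

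Genes near Cntnap4 on chromosome 8 were compared with the rest of the genome. Within 10 Mb, 167 genes were tested, 0 passed the limma threshold and 23 (13.8%) had an unadjusted p under 0.05, against 14.3% elsewhere (Fisher's exact test, two-sided p = 0.912). As a list they were lower in KO by a small amount, with a median log2 fold change of -0.06 and a camera p of 0.0398, and the p was 0.190 with an estimated correlation. The camera p was 0.0615 with the replicate block, 0.152 without WT2, 0.162 without KO3 and 0.622 for a window of 5 Mb. Necab2, a neuronal calcium-binding protein gene chosen after its values were seen, had the smallest p of them, at 52.3 ± 20.6 FPKM in WT and 16.7 ± 6.72 in KO (adjusted p = 0.302).

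Fold changes followed gene length. Among 11815 protein-coding genes the median log2 fold change went from -0.25 for genes under 1 kb to 0.13 for genes over 8 kb, and Spearman's rho across genes, which are not independent replicates, was 0.405. The slope of a library's deviation on log2 gene length was negative in the 3 WT libraries (-0.032, -0.0048 and -0.035) and positive in the 3 KO libraries (0.040, 0.019 and 0.013). Median lengths were 1754 bases for the ribosomal list and 10768 bases for the autism list.

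**Figure D4:**
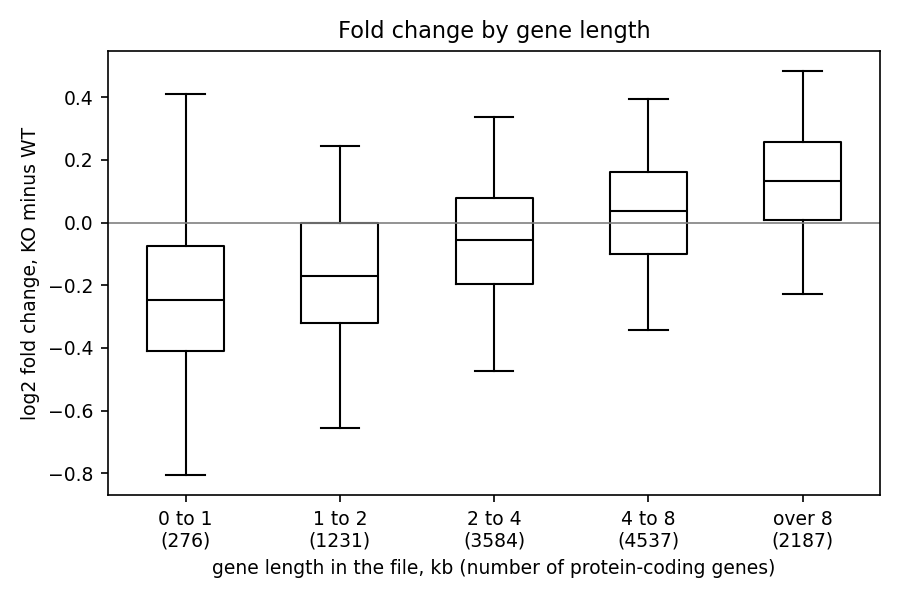
Log2 fold change (KO minus WT) of protein-coding genes by gene length in kb, with the number of genes in brackets; boxes span the quartiles, the line is the median and whiskers reach the 5th and 95th percentiles. Medians run from -0.25 to 0.13.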

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

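Alternatives with voom, with the trend on gene length removed and with WT3 and KO3 both left out were chosen after seeing the data. The cause of each move below was not tested, except that fewer genes or libraries enter some fits. The count of 1 gene past the threshold was 0 with no filter, quantile normalization, no variance trend, the replicate block, the length trend removed and both libraries numbered 3 left out, and 0 to 9 without one library. Rps27a kept its direction in all of these, with adjusted p up to 0.499. The count at an unadjusted p under 0.05 was 1219 with a mean FPKM of at least 5, 2852 with sample weights, and 879 to 2414 without one library. The 16 called lists became 0 with estimated correlations, 1 with fry, 10 with a mean FPKM of at least 5, 13 with the length trend removed, 20 with no filter, 20 with the replicate block, 22 without both libraries numbered 3 and 13 to 21 without one library. Each count is over all lists tested, so it can hide lists lost and others added, as with the length trend removed. With no filter the added lists were the hypothalamic (adjusted p = 0.000121), choroid plexus (0.0135), ependymal (0.0194) and border macrophage lists (0.00556), lower, and myelin (0.0490), higher. These calls use the preset correlation, and an estimated one was run only with the main settings and the block. Cntnap4 stayed lower and short of the threshold throughout (log2 fold change -1.11 to -0.79 without one library); the filter at 5 left it out. The camera p of the flanking genes was 0.622 at 5 Mb, 0.0600 at 20 Mb, 0.0508 with values rescaled to 1 common sum, 0.0615 with the replicate block, 0.107 with the length trend removed, 0.145 without both libraries numbered 3, and 0.0175 to 0.162 without one library.

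The replicate block ended the call of Rps27a, the fry call and the flanking call and added the lists given above. It changed no other call that was rerun with it, and calls adjusted over a list alone were not rerun. Log2 fold changes that turned were those of Hbb-bs (0.0023 with sample weights, 0.24 without both libraries numbered 3, -0.48 to 0.31 without one library), Hba-a1 (0.22 without both, -0.71 to 0.16 without one), Hba-a2 (0.33 without both, -0.84 to 0.28 without one), Cntnap1 (-0.016 to 0.37 without one, negative without WT1), Cntnap5b (-0.17 to 0.023, positive without KO2) and Foxj1 (-0.011 with sample weights, -0.16 without both, -0.11 to 0.083 without one). These 3 haemoglobin genes were positive without WT3 while Hbb-bt stayed at -0.13, and Foxj1 was negative without WT3, KO2 or KO3. The mitochondrially encoded list turned without WT3 (adjusted p 0.000634 to 0.944 without one library). Trh passed without WT3 (-3.46, adjusted p = 0.0392). Of 2845 values for 152 named genes, 2819 kept their direction and side of the threshold and 11 lost the call, all of Rps27a. All named genes but Rps27a were short of the threshold in the main fit. For them a kept side means only that they stayed uncalled, so this count is no measure of robustness. Rps27a was past the threshold in 8 of 19 alternatives. Of 333 values for the 16 lists, 277 kept both and 55 lost the call. Simulated changes of this design were recovered for 24.6% of genes at 1.5-fold, 79.0% at 2-fold and 95.2% at 4-fold. That simulation had independent genes of median spread and no shared shifts between libraries, so recovery in these data may be lower. Its many planted changes also made the Benjamini-Hochberg threshold easier to pass than in the real fit. Read depth (15933029 to 17789798 reads per library) was not tested as a limit.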

Other observations

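Tests of the striatal markers and of the range of the ribosomal protein genes were chosen only after the results were seen. The list of contactins, Cntnap genes, neurexins, neuroligins and other synaptic adhesion genes was not called (34 tested, median 0.07, camera adjusted p = 0.249), but 4 passed adjusted over the list alone and 0 over all genes. The adjustment over a list alone, here and for the next list, is not corrected across lists. Besides Cntnap4, which was lower, the members that passed were 3 higher genes, all chosen after their values were seen. Lrrtm2, a postsynaptic partner of neurexins, was at 11.8 ± 1.22 FPKM in WT and 16.7 ± 0.72 in KO, Cntn4, a contactin, at 5.90 ± 0.39 and 8.31 ± 0.56, and Slitrk4, a synaptic adhesion gene, at 5.67 ± 0.16 and 7.52 ± 0.36.

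Genes of the perineuronal net, the matrix around many inhibitory neurons, were not called either (12 tested, median -0.07, camera adjusted p = 0.566, direction up, so the median and the test differ in sign), and 4 passed adjusted over the list alone and 0 over all genes. Chosen after their values were seen, Hapln4, a link protein, was at 32.8 ± 1.48 FPKM in WT and 45.0 ± 4.19 in KO, Spock1 at 32.0 ± 3.63 and 41.2 ± 2.22 and Tnr, tenascin-R, at 11.9 ± 1.39 and 15.4 ± 0.97, while the proteoglycan Bcan was lower, at 69.2 ± 9.97 and 52.3 ± 1.33.

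The 6 libraries can be split into 3 and 3 in 10 ways, too few for a share under 0.05. For genes past the threshold, 1 of the 10 splits gave as many, with 1 in the real split and at most 0 in the others. For called lists, 5 of the 10 gave as many, with 16 in the real split and at most 23 in the others. For the flanking genes, 1 of the 10 gave as small a camera p, with 0.0398 in the real split and at least 0.0435 in the others. Of the 9 other splits, 3 also part all 3 replicate pairs and called 13 to 18 lists, and the 6 that part 1 pair called 7 to 23. At an unadjusted p under 0.05 the real split gave 1872 genes and the others at most 1554. The 3 others that part all 3 pairs gave 188 to 349 genes, and the 6 that part 1 pair gave 169 to 1554.

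The lower ribosomal protein genes in KO were set against the trend of fold change with gene length, since most are short. With that trend removed from each library, the median log2 fold change of the list was -0.22, against -0.30 before, and the list stayed called (camera adjusted p = 5.39e-13), so removing the trend took away part of the size and left the call. Without WT1, the library farthest from the others, the median was -0.32. RNA quality, GC content and genotype stay open as untested explanations, and the call needs the preset correlation. As a hypothesis, the shift may belong to the libraries' preparation or to the knockout, and these data do not decide between them.

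Of 22 tested striatal markers, 20 had WT3 and KO3 as the highest of 6 libraries. These libraries were picked because the markers are high in them, so this count restates the pattern; as a hypothesis that was not tested independently, it may come from striatal tissue in the dissected piece. The most abundant, Penk, was at 250 FPKM in WT3 and 98.3 in KO3, against at most 138 elsewhere; 18 of the 22 were at a mean of at least 1 in those 4 libraries and 10 are in other lists too. Overall scaling was argued against, since the median gap stayed at 2.19 on the log2 scale after quantile normalization. A difference in anatomy between animals stays open, and no biological explanation was tested.

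The lower Rps27a in KO lay outside the range of its family, with a log2 fold change -0.81 from that of the lowest of the 75 other ribosomal protein genes. Rps27a was picked because it passed the threshold, so this gap describes the gene and is no independent test. Movement of counted reads to its listed copies was argued against, since the 3 copies gained 0.361% of the reads that Rps27a lost per library. The handling of reads shared with these copies is not given, so a loss of such reads from the count was not tested. A sequence variant of another strain at this locus, which may keep reads from aligning, and an effect of the knockout stay open, as the table holds no sequence.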
